A study of Homo sapiens with 12 samples.

How the data were processed

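HEK293T cells, an established human embryonic kidney line, carried an APOA2 plasmid (control) or a SAMD4B plasmid together with the APOA2 plasmid. Each of 3 replicates per condition was measured as an Nm-seq library and as an input library, which gives 12 libraries in 4 groups. Nm-seq maps 2′-O-methylation, a methyl group on the ribose of RNA. Per the labels, total RNA was fragmented and 3′-end repaired, taken through 8 cycles of periodate oxidation, elimination and dephosphorylation and a final oxidation, then 5′ phosphorylated and built into small RNA libraries. A fragment that ends in a methylated ribose resists the oxidation. The labels repeat this protocol for the input libraries and do not say which steps the inputs skipped.

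The submitters' processing notes list cutadapt 1.9.1, Bowtie2 2.2.4, bedtools 2.24 and the genome build hg19. The role of each tool, the removal of duplicate reads, the calling of sites and its thresholds are not given in the sources used here. The deposited table held 12535 lines, which came to 4080 distinct sites once repeated exon entries were merged. Per the file headers, the authors gave a read count and a coverage signal for each site in each library, as whole numbers with no normalization. The meaning taken here, that the count is of reads whose end lies at the site and the coverage is of reads over it, is inferred from the assay and from counts that never exceeded the coverage. The deposited fraction was the count over the coverage of the same library, within 1e-06 at all 4080 sites. The deposited ratio of Nm-seq over input was the Nm-seq fraction over the input fraction, or 1 plus the Nm-seq fraction where the input fraction was 0. The authors' score per site was a signed fold between the means of that ratio in the groups. Where 1 group's mean was 0, the score was 1 plus the other mean, with a sign. The authors' p-value, unadjusted in the deposited table, was recomputed within 1e-06 from an equal-variance test on the ratios at the 3504 sites where that test is defined. At the other 576 sites the ratios had no spread, and the deposited p-value was 1.

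No site had a maximum below 10 counts over the 12 libraries, and the lowest fraction beside a count of 10 or more was 0.2. At 781 sites no Nm-seq library reached 10 counts, so these sites were listed through an input library. The highest count in any library was 37 and the highest coverage was 51. Positions in the deposited table count from 0: 108 listed exons on these strands start at a site when positions are read so, and 0 end at one. All positions here are counted from 1 in hg19, and exons are those of the deposited table. The annotation at hand was of GRCh38, so it served only to update gene symbols: 2268 of 2276 gene identifiers matched and 112 symbols were updated. Of the sites, 2765 carried 1 symbol, 114 carried several and 1201 carried none. RNA classes (protein-coding, snoRNA, snRNA, rRNA, other non-coding, pseudogene) came from the biotype of the listed gene.

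Total counts over the 4080 sites were 43857, 42009 and 42831 in control Nm-seq replicates 1 to 3, and 45883, 42480 and 43468 in the SAMD4B+APOA2 Nm-seq replicates. The SAMD4B+APOA2 inputs held 14130, 14133 and 14382 counts, and control input 2 held 14870. These totals cover the listed sites alone, and the number of reads in each whole library is not given. Control inputs 1 and 3 held the same value at each of the 4080 sites, with 16 counts and 39 covering reads in all, so they were 1 library in content. They were left out of the fits as nearly empty, which is a departure from the planned 12 libraries: 4 inputs and 10 libraries remained. No label separates these 2 libraries from the others.

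Sites were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, sites with at least 10 counts in at least 3 libraries, two-sided, Benjamini-Hochberg at 0.05) in R 4.3.3. Genes were compared by the sum of counts over their sites with a single symbol, which gave 2140 genes before the filter. The standard error of a log2 fold was its size over the square root of the quasi-F. Nm-seq was compared with input within each condition, and between conditions as an interaction, in a fit of 4 groups over the 10 libraries. The control condition then had 1 input, which is assumed to vary like the other groups. Lists were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry of limma 3.58.1. DESeq2 1.42.0 and voom with sample weights were run beside edgeR. Single values were compared by exact permutation tests, two-sided, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 drew the plots. With 3 libraries against 3, the smallest exact p is 0.1. A fold against a group with 0 counts in all libraries is given as "at least", from a floor of 3 counts over the group. Intervals are exact at 95%, and intervals and floors cover counting error only, since reads are not independent molecules. The labels do not say whether the replicates came from separate cultures. They may be technical, and p-values then measure only the spread between these samples.

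The tests, alternatives, lists and the rule for naming genes were fixed before the data were examined. The rule names each APOA2 and SAMD4B site, then the 10 largest rises and falls past 0.05 with groups that do not overlap (at most 1 per gene, up to 5 each way from the gene fit). Where fewer than 10 pass, it names the 10 lowest p-values. It also names 2 members of each list with 5 or more measured genes, and the 5 sites and 5 genes with the highest means. Of the latter 5 genes 3 are given; the other two, and 1 further gene that the rule names, are not reported here. The 19 lists held Nm methyltransferases and box C/D core proteins, deadenylation and mRNA decay, apolipoproteins, cholesterol and fatty acid synthesis, ribosomal proteins, mitochondrially encoded genes, ribosomal RNA, small nuclear and nucleolar RNAs, snoRNA host genes, histones, interferon and RNA sensing, immune checkpoints, heat shock, cell cycle, translation factors, splicing factors, glycolysis, hepatocyte markers, and HeLa, immune and fibroblast markers.

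Alternatives set in advance were the replicate number as a block, DESeq2, its size factors within edgeR, no filter, a stricter filter, the plasmid genes left out, voom, other ways to combine or select sites, and each library left out in turn. Alternatives chosen after seeing the data were the test without its Poisson bound, total counts without TMM and size factors in the fit with inputs, odds of the count against the rest of the coverage (coverage of 10 or more), all 12 libraries without TMM, and the 6 SAMD4B+APOA2 libraries alone. The steps were tested on simulated data in which 200 sites were changed. Counts were drawn with Poisson noise, and with binomial noise for the odds test. Nm-seq replicates lay closer together than Poisson noise, so the recovery given here need not hold for the data. Changing 200 sites at once also eases the Benjamini-Hochberg threshold, so changes at only a few sites would be recovered less often. At 2-fold, edgeR recovered 70% of the changed sites between conditions, or 65% with counts capped at the highest of the file, and made 5 false calls among 1950 unchanged sites. At 4-fold it recovered 100%. DESeq2 recovered 18% at 2-fold and 97% at 4-fold. The odds test between conditions recovered 25% at 8-fold. For Nm-seq against input, the simulation used the 6 SAMD4B+APOA2 libraries alone (1917 sites, capped counts), where edgeR recovered 24% at 2-fold and 82% at 4-fold. The fit of 10 libraries and the odds test of Nm-seq against input were not simulated.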

Results

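The data were 4 groups of 3 libraries from HEK293T cells: Nm-seq and input, each with the APOA2 plasmid alone (control) or with SAMD4B and APOA2 plasmids. APOA2 is an apolipoprotein of high-density lipoprotein, and SAMD4B is an RNA-binding protein of the Smaug family. Of the 4080 sites, 2147 (52.6%) lay in exons of protein-coding genes, 922 (22.6%) outside listed exons, 400 in pseudogenes, 165 in snoRNA genes, 40 in snRNA genes, 35 on the mitochondrial chromosome and 30 in rRNA genes. The base at the site was A at 1480 sites (36.3%), C at 1119 (27.4%), G at 777 (19.0%) and T at 704 (17.3%). Total counts were 42899 ± 926 (SD, n = 3) in control Nm-seq, 43944 ± 1751 (n = 3) in SAMD4B+APOA2 Nm-seq and 14215 ± 145 (n = 3) in SAMD4B+APOA2 input. Control input 2 held 14870 counts, and control inputs 1 and 3 held the same 16 counts, so control input values below have no replicates. Nm-seq replicates of a group differed by less than sampling noise (chi-square over degrees of freedom 0.555 to 0.664) but were not identical, and were counted separately. The sites with the highest mean counts over the 6 Nm-seq libraries were in FUT8 (36.5 ± 0.55), REPS1 (36.5 ± 0.84), RPS2P46 (36.2 ± 0.98), DOCK1 (36.2 ± 0.75) and RBM15 (35.8 ± 0.75). Among genes, EIF3A (100.5 ± 8.04), SMC1A (99.7 ± 5.28) and DNMT1 (99 ± 1.67) were among the 5 with the highest sums of counts, as means ± SD over 6 libraries.

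Reads over SAMD4B differed between the conditions at 1 of its sites, which checks the label of the plasmid. At position 39860423 of chromosome 19 (plus strand, base G, exon 39860296 to 39860765), the Nm-seq coverage was 2, 8 and 6 reads with the SAMD4B plasmid (5.33 ± 3.06, SD, n = 3) and 0 in the 3 control libraries. This was at least 5.26-fold higher, and the exact two-sided p was 0.1, the smallest that 3 libraries against 3 allow. In the inputs, 37, 35 and 37 reads covered the site with SAMD4B (36.3 ± 1.15) against 4 in control input 2. Scaled on the total coverage, this was a ratio of 9.55 (exact 95% interval 3.63 to 35.7). With 1 read added on each side, the ratio ranked 1 of the 1691 sites with a coverage of 10 or more in an input. This SAMD4B site was 1 of 4 sites covered in all 3 SAMD4B+APOA2 and in 0 control Nm-seq libraries. The other three, in RNY4P5, NOP56 and an exon shared by SNORA8 and TAF1D, were chosen after their values were seen and had at most 2 covering reads. The count at the SAMD4B site was 0, 2 and 2 against 0 in each control (exact p = 0.4). The second SAMD4B site, at 39838717 (base A, exon 39833109 to 39839029), had 6.67 ± 2.31 counts with the SAMD4B plasmid and 8.33 ± 1.53 in the control (exact p = 0.6), and 0 reads in the 3 SAMD4B+APOA2 inputs against 1 in control input 2. Summed over both sites, SAMD4B had 8.0 ± 3.46 against 8.33 ± 1.53 counts (log2 fold -0.10, SE 0.33; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.999). Its log2 fold was 0.04 without control Nm-seq 1 and 0.24 without SAMD4B+APOA2 Nm-seq 1.

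The design asks about the APOA2 mRNA when SAMD4B is overexpressed. Neither the counts at the APOA2 sites nor their sum passed a test between the conditions. At 161192743 of chromosome 1 (minus strand, base A, exon 161192709 to 161192840), the Nm-seq count was 14.7 ± 2.1 with SAMD4B and 13.3 ± 1.5 in the control (SD, n = 3 each). The log2 fold was 0.11 (SE 0.17), and the adjusted p was 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At 161193135 (minus strand, base T, exon 161192709 to 161193403), the counts were 6.0 ± 2.0 and 8.33 ± 2.31 (exact p = 0.4), below the filter on low counts. Summed over both sites, APOA2 had 20.7 ± 0.58 against 21.7 ± 3.79 counts (log2 fold -0.11, SE 0.14; adjusted p = 0.999 by edgeR). Without control Nm-seq 2 the log2 fold of APOA2 was 0.07.

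The coverage of both APOA2 sites was lower in each SAMD4B+APOA2 Nm-seq library than in each control. It was 37.7 ± 0.58 against 39.7 ± 1.15 reads at 161192743 and 7.0 ± 1.0 against 10.0 ± 1.0 at 161193135 (SD, n = 3; exact p = 0.1 for each). Over all sites, the groups' coverage did not overlap at 6.74% (166 higher and 109 lower with SAMD4B). Chance gives 10% for values without ties. Coverage is in low whole numbers with ties, so its chance share is lower and was not computed. Input coverage of the APOA2 sites was 45.3 ± 1.53 against 47 reads and 11.3 ± 1.15 against 13 reads. Coverage of 161192743 lay near the highest of any site, 51 reads, which limits what it can show about the amount of APOA2 RNA.

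**Figure D1:**
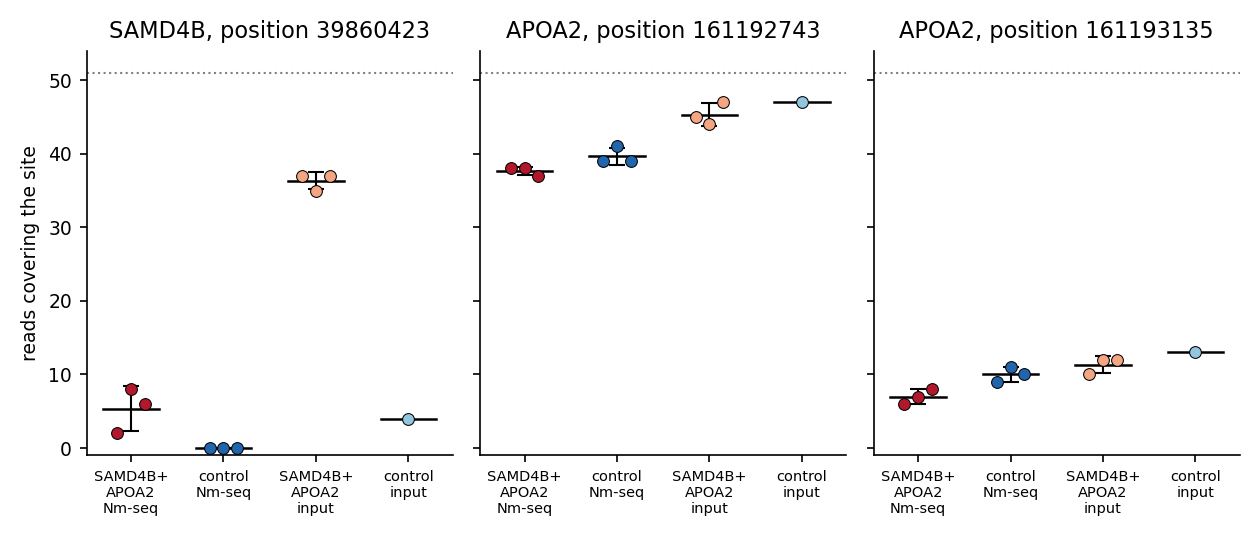
Reads covering the site per library (vertical axis) at SAMD4B position 39860423 and APOA2 positions 161192743 and 161193135, by group; points are libraries, bars are means ± SD, and the dotted line is the highest coverage of any site, 51 reads. At SAMD4B the 3 control Nm-seq libraries lie at 0 and the 3 SAMD4B+APOA2 inputs at 35 to 37 reads.

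Across all Nm-seq sites, SAMD4B overexpression was compared with the control to ask whether methylation signal moved anywhere. No site passed the test. The 3 lowest p-values were at a site in OAS3, an interferon-induced oligoadenylate synthetase, an unnamed site at 48423845 of chromosome 8, and a site in GNAS, a G-protein alpha subunit. The OAS3 site (chromosome 12, 113409480, exon 113407414 to 113411054) had 13.0 ± 1.0 counts with SAMD4B and 5.33 ± 0.58 in the control, and the GNAS site (chromosome 20, 57466885, exon 57466420 to 57466920) had 13.3 ± 1.15 and 5.67 ± 3.22. The unnamed site had 6.33 ± 3.51 counts with SAMD4B and 14.0 ± 3.0 in the control (log2 fold -1.16, SE 0.31; unadjusted p = 0.00221 in edgeR). The log2 folds of OAS3 and GNAS were 1.24 (SE 0.27) and 1.19 (SE 0.33), with unadjusted p of 0.00211 and 0.00258 in edgeR. Of 2150 tested sites, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 (13 at an unadjusted p under 0.05). DESeq2 called 0 (3 unadjusted, in OAS3, in GNAS and at the unnamed site on chromosome 8) and voom called 0 (98 unadjusted). Chance gives a share of 0.05 of the tested sites, more than these 13, so edgeR's test was conservative here. Without its Poisson bound, edgeR had 114 sites at an unadjusted p under 0.05 and called 0. Others of the 10 lowest p-values, all with an adjusted p of 1 in edgeR, were spread over genes of unlike function. Counts were higher with SAMD4B in the poly(A)-binding protein PABPC1 (15 ± 2.65 against 8.67 ± 3.06), the elongation factor EEF1A2 (13.0 ± 0 against 7.33 ± 1.53) and AAMP (13.3 ± 5.13 against 7.67 ± 2.08). The site in BTAF1, an ATPase that acts on the TATA-binding protein, had 10.3 ± 3.22 against 16.7 ± 1.53 counts. The other unnamed sites were at 9827553 of chromosome 21 (1.04) and 144835909 of chromosome 1 (0.67). On simulated counts at this depth, capped at the highest count, 65% of sites changed 2-fold and 100% of sites changed 4-fold were recovered. Those counts had Poisson noise, whereas replicates here lay closer together, so the recovery need not hold for these data. The simulation also changed 200 sites at once, which eases the adjusted threshold. Changes of 2-fold at only a few sites, smaller changes, and changes at sites near the highest count could be missed.

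**Figure D2:**
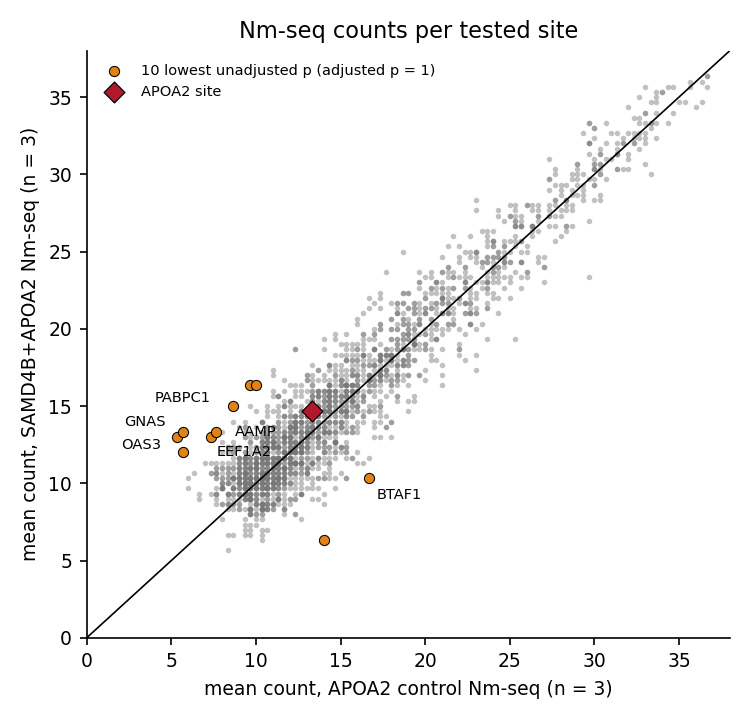
Mean count of each of the 2150 tested sites in control (horizontal axis) and SAMD4B+APOA2 (vertical axis) Nm-seq libraries, n = 3 each; the line marks equal counts, the diamond is APOA2 site 161192743, and the circles are the 10 sites with the lowest p-values, of which 6 are labelled. No site passed the adjusted threshold, and no count exceeded 37.

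Summed by gene, no gene passed the test either. OAS3 (log2 fold 1.23), the co-chaperone FKBP4 (0.95; 16.7 ± 3.06 against 8.33 ± 3.06 counts), DNMBP, a guanine nucleotide exchange factor (0.83; 18.3 ± 1.53 against 10.0 ± 2.0), AAMP (0.75) and BTAF1 (-0.72) were the 5 genes at an unadjusted p under 0.05. Of 1445 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0. DESeq2 called 0 (3 unadjusted: OAS3, FKBP4 and DNMBP) and voom called 0 (77 unadjusted). The 5 genes in edgeR were again fewer than the share of 0.05 that chance gives. Without its Poisson bound, edgeR had 78 genes at an unadjusted p under 0.05 and called 0. The next lowest p-values belonged to RBM23 (log2 fold -0.56), RNF169 (-0.63), PPP2CA (0.47), CRTC1 (0.58) and ZNF503 (0.56), with an adjusted p of 0.999 for all 10.

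The 10 lists with at least 5 measured genes had 0 members called over all genes and 0 adjusted over the list alone by edgeR (DESeq2 and voom called 0 of all genes). The deadenylation and mRNA decay list, to which the Smaug family is linked, had 5 of 8 genes with log2 folds below 0, with TOB2 at -0.66 and SMG1 at -0.20 (camera adjusted p = 0.607, fry adjusted p = 0.641). Cytosolic ribosomal proteins had 13 of 18 genes below 0, with RPL37A at -0.46 and RPL15 at 0.42 (camera adjusted p = 0.607). The ribosomal RNA list was filled by the form of the symbol and also held genes not classed as rRNA. Of its 30 genes, 19 were above 0, with the 5S genes RNA5S9 at 0.46 and RNA5S6 at 0.41 (camera adjusted p = 0.607). The small nuclear and nucleolar RNA list was filled in the same way and also held other RNAs and pseudogenes, such as RPPH1 and RNU6-17P. Its 67 measured genes divided into 34 above and 33 below 0, with RNVU1-19 at -0.63 and SNORD3B-1 at -0.62 (camera adjusted p = 0.607). Their median log2 fold (0.0043) and mean (-0.03) differed in sign, and the test pointed down. Fry's mixed p, for change in either direction, was 0.0801 after adjustment over the 10 lists (0.00801 unadjusted, the smallest of them). The 7 snoRNA host genes (SNHG1 -0.17, GAS5 -0.10) and the 8 heat shock genes (DNAJA1 -0.32, CALR -0.25) pointed down in camera (adjusted p = 0.607 for each). The 7 cell cycle genes (CCNB2 -0.30, RRM1 0.09; camera adjusted p = 0.822) also pointed down, although their median was 0.03 and their mean -0.01. Histones (6 genes; H2AC8 -0.17; camera adjusted p = 0.607), splicing factors (18 genes; U2AF2 0.27, HNRNPU 0.24; adjusted p = 0.784) and translation factors (10 genes; PABPC1 0.31, EEF1A1 0.26; adjusted p = 0.607) pointed up. H2AC8 was at 0.145 without SAMD4B+APOA2 Nm-seq 3, and GAS5 at 0.006 without control Nm-seq 1 and 0.04 without SAMD4B+APOA2 Nm-seq 1. With the highest site of each gene in place of the sum, RNA5S9 was at -0.036 and SNHG1 at 0.056. Adjusted camera p-values ran from 0.607 to 0.822, those with an estimated correlation from 0.712 to 0.828, and those of fry from 0.641 to 0.744.

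No measure of the methylation signal as a whole passed a test between the conditions, where the smallest exact p is 0.1. The median count per site was 9.67 ± 0.58 with SAMD4B and 10.0 ± 0 in the control (exact p = 1), and the total count gave an exact p of 0.5 (SD, n = 3 each; all exact tests two-sided). Sites above 0 numbered 3698 ± 7.2 with SAMD4B and 3714 ± 31.9 in the control (exact p = 0.7). The sign of this difference turned at higher counts: sites above 7 counts were 88.3 more with SAMD4B, and 2884 sites with SAMD4B against 2769 in the control reached 10 counts in any library. In all, 3488 sites (85.5%) were above 0 in all 6 Nm-seq libraries. The mean fraction per site was 0.803 ± 0.003 and 0.804 ± 0.004 (exact p = 1), and the median fraction was 1.0 in all 6 libraries. Pooled over all sites, 84.7 ± 0.14% of covering reads were counted with SAMD4B and 83.9 ± 0.87% in the control, higher in each SAMD4B+APOA2 library (exact p = 0.1). The 5 sites above 0 in each SAMD4B+APOA2 and in no control Nm-seq library were in RNY4, RNY4P5, RNU6-17P, RNU6-7 and at 50626335 of chromosome 19, with mean counts of 1.0 to 1.67; they were chosen after their values were seen. The reverse held at 7 sites, of which SERBP1 (67890572 of chromosome 1) had the highest mean, 3.0 counts. Shares of counts by base and RNA class gave 26 tests, with a smallest adjusted p of 0.812. Sites on the mitochondrial chromosome took 0.438 ± 0.013% of counts with SAMD4B and 0.471 ± 0.015% in the control, and sites in snRNA genes 0.43 ± 0.013% and 0.453 ± 0.007% (exact p = 0.1 for each, unadjusted). Protein-coding exons took 66.0 ± 0.71% and 65.1 ± 0.70% (exact p = 0.3).

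Nm-seq was compared with input to show at which sites they differed. Each listed site reached 10 counts in some library, 3299 in an Nm-seq library and 781 in an input alone. High Nm-seq values at the first set and high input values at the second are therefore in part built in. The labels do not say which steps the inputs skipped, so the differences are not assigned to the oxidation. With SAMD4B and APOA2, sites in protein-coding exons took 66.0 ± 0.71% of Nm-seq counts but 22.1 ± 0.17% of input counts (SD, n = 3 each), while snoRNA genes took 1.01% of Nm-seq and 14.4 ± 0.44% of input counts. Sites at A took 41.6% of Nm-seq and 25.5 ± 0.84% of input counts, and sites at T 13.1% and 24.1 ± 0.74%. Of the reads covering protein-coding sites, 95.3 ± 0.13% were counted at the site in Nm-seq and 31.8 ± 1.7% in input. For rRNA sites these shares were 25 ± 2.39% and 5.55 ± 0.35%, and for snRNA sites 33.8 ± 0.16% and 31.1 ± 0.60%. For snoRNA sites they were 51.1 ± 2.98% and 52.4 ± 0.07% (exact p = 1; exact p = 0.1 in each other class, n = 3). The control Nm-seq libraries gave 95.2 ± 0.13% for protein-coding and 50.8 ± 0.48% for snoRNA sites.

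**Figure D3:**
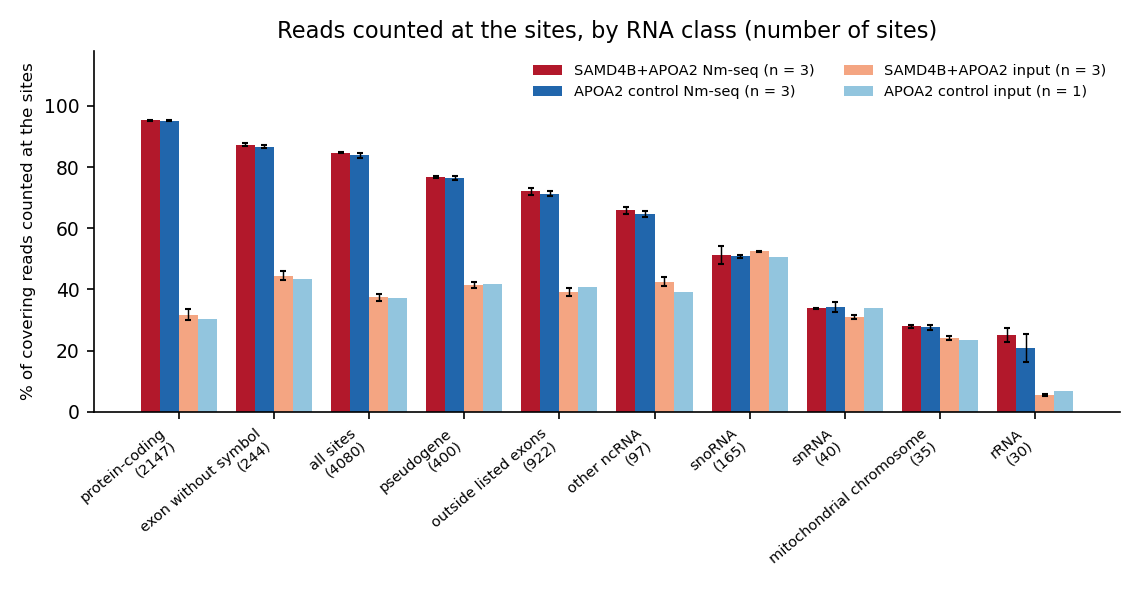
Percent of covering reads counted at the sites (vertical axis) by RNA class, for Nm-seq and input libraries of both conditions; bars are means and error bars the SD (n = 3, and n = 1 with no error bar for control input), with the number of sites in parentheses. In protein-coding exons Nm-seq libraries lie between 95.1% and 95.5% and inputs between 30.2% and 33.6%, whereas snoRNA sites lie between 47.7% and 53.2% in all groups.

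Tested site by site, counts in Nm-seq were higher than in input mostly in protein-coding exons, and most of the tested snoRNA and snRNA sites were lower. With SAMD4B, 1330 of 2551 sites passed, 761 higher and 569 lower in Nm-seq, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Protein-coding exons held 553 of the 761 higher calls. Of the 569 lower calls, 227 lay outside listed exons, 110 in snoRNA and snRNA genes, 85 in pseudogenes and 70 in protein-coding exons. Scaling changed how many sites were higher: total counts without TMM gave 2206 calls (1690 higher, 516 lower), and size factors gave 1965 (1432 higher, 533 lower). The median log2 fold over all tested sites was 1.12 with TMM and 2.01 without, and calls were tested against a log2 fold of 0 under each scaling. The 10 largest rises in fitted fold under the naming rule included PRPS1, a phosphoribosyl pyrophosphate synthetase (chromosome X, 106888458; 28.0 ± 1.0 counts in Nm-seq and 0 in the 3 inputs, at least 4.14-fold, adjusted p = 7.55e-06 in edgeR), ABHD10 (chromosome 3, 111710609; 27.3 ± 2.52 counts), TADA1 (chromosome 1, 166826881; 25.7 ± 1.15) and PLEKHA5 (chromosome 12, 19436605; 25 ± 1.0). The rises at BRD7P5 (chromosome 13, 95410781; 27.3 ± 3.79), the dynein heavy chain DYNC1H1 (chromosome 14, 102502886; 23.7 ± 1.53) and the splicing factor SRSF6 (chromosome 20, 42089398; 22.7 ± 0.58, at least 3.35-fold) were also among them, with unnamed sites at 24977254 of chromosome 6, 70255185 of chromosome 16 and 74621919 of chromosome 7. All 10 had 0 counts in the 3 inputs, where mean coverage ran from 0 reads at BRD7P5 and 0.33 at PLEKHA5 to 7.33 at PRPS1 and 15.7 at the site on chromosome 6. The largest falls were at SNORD99, a box C/D snoRNA (chromosome 1, 28905265; 31.7 ± 2.08 counts in input and 0 in Nm-seq, at least 112-fold without TMM and 214-fold with it, adjusted p = 7.55e-15 in edgeR), SNORA5C (chromosome 7, 45144506; 28.7 ± 2.08), SNORD90 (chromosome 9, 125642504; 26.7 ± 4.04) and the exons shared by RPL23 and SNORA21 (chromosome 17, 37009117; 28.7 ± 1.53) and by RPL17 and SNORD58A (chromosome 18, 47017654; 25.3 ± 0.58, at least 89.2-fold without TMM and 171-fold with it). Sites in listed exons of NOP56 (chromosome 20, 2635845, 27.0 ± 2.0 in input) and of SNHG3 (chromosome 1, 28834084, 26.7 ± 2.52) fell as well. NOP56 is a box C/D core gene and SNHG3 a host gene. The symbol comes from the listed exon alone and does not tell which RNA of the locus gave the reads. Unnamed sites at 184043561 of chromosome 3, 134365960 of chromosome 9 and 83817008 of chromosome 4 also fell. Mean Nm-seq coverage with SAMD4B was 0 to 0.33 reads at these 10 falls. The odds of the count against the rest of the coverage therefore rest on almost no Nm-seq reads there and say little about these sites.

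By group, 94 of 108 snoRNA sites were lower in Nm-seq and 2 higher, with a median log2 fold of -6.65 with zeros at the floor (camera adjusted p = 3.62e-41; 0.00064 with an estimated correlation). Of 17 snRNA sites, 16 were lower (adjusted p = 6.91e-09; 0.00187 with an estimated correlation). Of 1458 protein-coding sites, 553 were higher and 70 lower (median 0.83; camera adjusted p = 4.78e-26; 0.000746 with an estimated correlation), and without TMM 1240 were higher and 43 lower. Other non-coding genes had 35 of 58 sites lower and 7 higher, and the mitochondrial chromosome 11 of 16 lower (adjusted p = 0.0077 and 0.0149 with an estimated correlation). Outside listed exons, 227 of 508 sites were lower and 88 higher (0.0324 with an estimated correlation), and the median log2 fold at the floor turned from -0.61 to 0.33 without TMM. Pseudogenes had 59 higher and 85 lower of 235, with the test down (0.0228 with an estimated correlation) and the median above 0, at 0.30. Exons without a symbol had 52 higher and 31 lower of 149 sites (camera adjusted p = 0.64). On the share of covering reads, the calls in each class were mostly higher in Nm-seq, also where counts were mostly lower. Over 3191 sites the odds test called 1750 higher and 66 lower. Among the sites of the count test, it called 16 of 108 snoRNA sites higher and 6 lower, 8 and 1 in snRNA genes, 23 and 2 in other non-coding genes, and 9 and 1 on the mitochondrial chromosome; 52 of the 108 snoRNA sites had 0 counts in Nm-seq. It called 184 higher and 10 lower outside listed exons, 123 and 2 in pseudogenes, 86 and 2 in exons without a symbol, and 1028 and 7 in protein-coding exons.

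**Figure D4:**
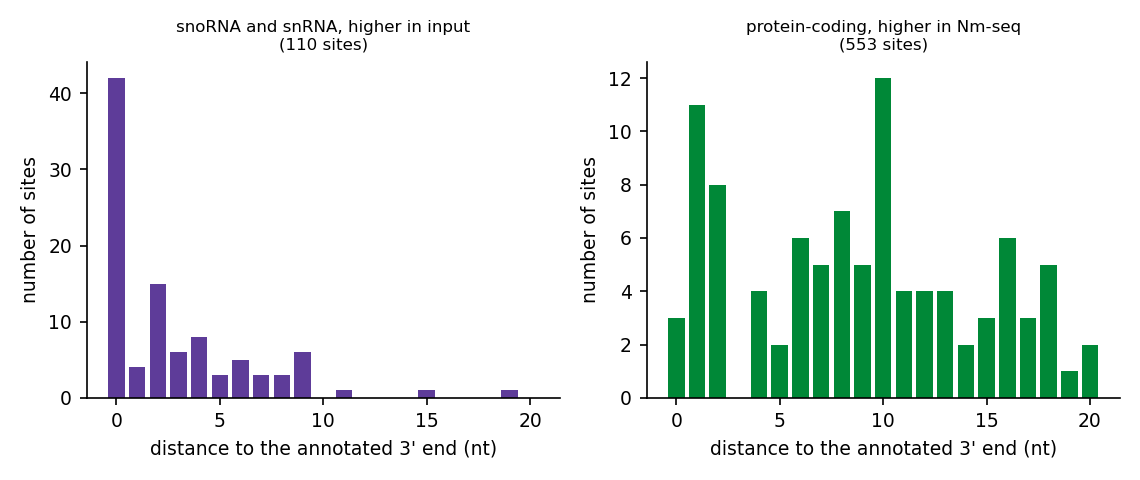
Number of sites (vertical axes, on different scales) by distance in nucleotides from the annotated 3′ end of the listed exon (horizontal axes, up to 20 nucleotides). Among snoRNA and snRNA sites higher in input, 42 of 110 lie on the 3′ end itself (43 of all 125 tested sites of these genes), and among protein-coding sites higher in Nm-seq 3 of 553 (7 of all 1458).

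Of the lists, small nuclear and nucleolar RNAs had 162 of 205 sites lower and 4 higher (162 and 5 adjusted over the list alone). The camera adjusted p was 4.91e-42, and 0.000568 with an estimated correlation. Of the 162 lower sites, 110 lay in snoRNA or snRNA genes and 52 elsewhere. SnoRNA host genes had 40 of 47 sites lower and 3 higher (41 and 3 adjusted over the list alone). Their camera adjusted p was 0.000746 with an estimated correlation. Of these 40 lower sites, 9 lay in exons that also belong to a snoRNA or snRNA gene. Ribosomal proteins had 36 of 57 sites lower and 9 higher (36 and 11 adjusted over the list alone; camera adjusted p = 7.41e-11, and 0.000746 with an estimated correlation), and 22 of these 36 lay in exons that also belong to a snoRNA or snRNA gene, as at RPL23 and RPL17. In the ribosomal RNA list, 22 of 25 sites were lower and 0 higher (23 and 0 adjusted over the list alone). The camera adjusted p was 0.000996 with an estimated correlation. That list was filled by the form of the symbol, and only 2 of all tested sites were classed as rRNA. Nm methyltransferases and box C/D core genes had 4 of 6 sites lower and 1 higher (the same numbers adjusted over the list alone). Of these 4 lower sites, 1 lay in an exon that also belongs to a snoRNA or snRNA gene. The camera adjusted p of 0.0126 was lost with an estimated correlation (adjusted p = 0.0599). Lists with no shift in camera were the cell cycle (3 of 8 sites higher, 1 adjusted over the list alone; adjusted p = 0.139), mRNA decay (4 of 8 higher, 4 adjusted over the list alone; 0.233) and histones (4 higher and 1 lower of 7, 4 and 1 adjusted over the list alone; 0.355). Splicing factors (7 higher and 2 lower of 22, 7 and 2 adjusted over the list alone; 0.355) and heat shock genes (4 higher and 3 lower of 18, 3 and 3 adjusted over the list alone; 0.932) had none either. Translation factors had 6 higher and 7 lower of 21 (7 and 7 adjusted over the list alone, camera adjusted p = 0.331). Their median log2 fold was 0.41 but their mean -0.67, and the test pointed down. Of the 7 lower sites, 5 lay in exons that also belong to a snoRNA or snRNA gene.

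In the control, the same kinds of sites differed between Nm-seq and its single usable input. Of 2551 sites, 600 passed in edgeR (78 higher, 522 lower), and 1500 without TMM (1014 higher, 486 lower) or 992 with size factors (495 higher, 497 lower). The control shared 516 of the 569 lower calls of the SAMD4B+APOA2 libraries (116.4 expected of independent lists) and 57 of the 761 higher calls (23.3 expected), with 0 calls in opposite directions. Of the SAMD4B+APOA2 calls, 723 of 761 higher (95.0%) and 566 of 569 lower (99.5%) had the same sign in the control. The difference in enrichment between the conditions, tested as an interaction, passed at 0 sites in edgeR (94 at an unadjusted p under 0.05; smallest adjusted p 0.283), and no other tool was run on it. Without SAMD4B+APOA2 input 1 it passed at 1 site, in the ubiquitin ligase RNF125 (chromosome 18, 29625675; adjusted p = 0.0468, with smallest adjusted p-values of 0.161 to 1 under the other alternatives), which was chosen after its value was seen. Inputs alone differed between the conditions at 0 sites in edgeR (76 at an unadjusted p under 0.05), and without SAMD4B+APOA2 input 1 at 2 sites, lower with SAMD4B in RNF125 (adjusted p = 0.028) and PANK3 (chromosome 5, 167988475; adjusted p = 0.0433), with smallest adjusted p-values of 0.0882 to 1 under the other alternatives.

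The authors' deposited table compared fold over input between the conditions. In the authors' deposited table, APOA2 site 161192743 had a mean fold over input of 3.69 with SAMD4B and 6.61 in the control (signed fold -1.79, p = 0.639), and APOA2 site 161193135 had a signed fold of -1.20 (p = 0.259). Input counts at 161192743 were 0, 0 and 2 with SAMD4B and 1 in control input 2. Each of its 2 means therefore rested largely on 1 library. In the others the input fraction was 0 and the ratio was 1 plus the Nm-seq fraction. For SAMD4B site 39860423 the authors' deposited table gave a score of 1.74 (p = 0.173). This is not a ratio of means: the control mean was 0, so the score was 1 plus the SAMD4B mean of 0.738. The authors' deposited table held 198 sites with p under 0.05, 94 higher and 104 lower with SAMD4B, where chance gives 175.2 over the 3504 sites with a defined test. After Benjamini-Hochberg adjustment 23 passed, and 12 of these had a listed p of 0. Mean fold over input in the authors' deposited table was 2.29 with SAMD4B and 1.9 in the control, while the medians over sites were 1.93 and 1.96. By library, the means over sites in the authors' deposited table were 2.25 to 2.35 with SAMD4B, 2.3 in control 2, and 1.71 and 1.7 in controls 1 and 3. Of these 198 sites, the count test covered 109, and 2 of them had an unadjusted p under 0.05 in edgeR (0.7 expected of independent lists): PABPC1 and the unnamed site 9827553 of chromosome 21, chosen after their values were seen. In the authors' deposited table, control replicates 1 and 3 had an input fraction of 0 at 4065 sites, so that their fold over input could not exceed 2.0.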

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

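The settings without TMM, with size factors or odds in the comparisons with input, with all 12 libraries, with 6 libraries alone or without the Poisson bound were chosen after the result was seen. Apart from the values given here, results were taken as unchanged at 88 values with a setting changed and 169 with a library left out. For totals, means and shares of counts this meant a move smaller than the SD between libraries, so a sign could turn. For numbers of calls it meant a change within a set factor. Named sites and genes kept their direction and side of the threshold at 457 values with a setting changed and 423 with a library left out. With a library left out, shares of counts changed sign for A (-0.301 to 0.031 points), G (-0.076 to 0.369), pseudogenes (-0.141 to 0.1) and snoRNA genes (-0.05 to 0.007). Calls between the conditions stayed at 0 sites and 0 genes under each setting run, with smallest adjusted p-values down to 0.453 and 0.224. With the replicate number as a block, Nm-seq against input gave 1327 sites with SAMD4B and 587 in the control, and the other tests stayed at 0. Sites detected above the 25th percentile of counts (7) differed by 88.3 in place of -15.7. The mean fraction over sites above 0 in all 6 libraries differed by 0.004 in place of -0.0006, and the snRNA share of counts by -0.044 in place of -0.022 points; the cause was not tested. SAMD4B scaled on the library median (log2 fold 0.006) and APOA2 at its highest site (0.101) changed sign; the cause was not tested. Nm-seq against input with SAMD4B gave 2206 sites without TMM, 2205 with all 12 libraries and 427 with odds over the 524 sites covered in all libraries. For the control these were 1500, 1499 and 374, with 992 by size factors and 1439 by odds over 3191 sites. The 524 sites are fewer to test; for the other settings the cause was not tested.

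With each library left out in turn, the differences ran from -0.5 to 0 for the median count, 75 to 1776.5 for the total, -29 to 2 for sites detected, -0.0027 to 0.0008 for the mean fraction and 4 to 7 reads for the coverage of SAMD4B. Log2 folds ran from -0.197 to 0.066 for APOA2 and -0.3 to 0.243 for SAMD4B. APOA2 was 0.066 without control Nm-seq 2, and SAMD4B was 0.037 without control Nm-seq 1 and 0.243 without SAMD4B+APOA2 Nm-seq 1. The interaction ran from 0 to 1 sites, inputs from 0 to 2, and Nm-seq against input from 1154 to 1330 with SAMD4B and 587 to 601 in the control. Among named genes that did not pass, H2AC8 ran from -0.702 to 0.145 (without SAMD4B+APOA2 Nm-seq 3) and GAS5 from -0.338 to 0.04, above 0 without control Nm-seq 1 (0.006) or SAMD4B+APOA2 Nm-seq 1, and RNA5S9 (-0.036) and SNHG1 (0.056) changed sign at their highest sites; the cause was not tested. Of the 20 named sites of Nm-seq against input, 11 no longer passed by odds, but Nm-seq or input held at most 0.33 covering reads there, so this says nothing about them. Not run were another pseudocount, which counts do not use, a filter at 5 times the minimum, which no site can meet (sites above the median of the means were used), and control input 2 left out, which leaves no control input. Low counts limit single sites: no count exceeded 37, and 65% of 2-fold changes between conditions were recovered on simulated counts. Those had Poisson noise, which these data do not show, and 200 sites changed at once, which eases the adjusted threshold.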

Other observations

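Tests of the share of reads counted at the sites, of TMM scaling and of 3′ ends within a class, below, were chosen after the result was seen. Genes with many sites were the snoRNA hosts SNHG1 (11 sites) and GAS5 (10), the mitochondrial-like MTRNR2L8 (9) and MTRNR2L12 (8), and SMC1A, EIF3A, MACF1 and MALAT1 (6 each). Of 2043 protein-coding sites with 10 or more counts in an Nm-seq library, 13 lay on the 3′ end of the exon, 40 at 1 nucleotide from it and 51 at 2 nucleotides, against 2, 0 and 1 at the same distances from the 5′ end. The 3′ and 5′ ends may differ in how well reads there can be counted, which was not tested. Repeat-masked sequence held 908 sites (22.3%).

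Lists with fewer than 5 measured genes were not tested as lists, and 0 of their members passed in edgeR (0 in DESeq2 and 0 in voom over all genes). Among interferon and RNA-sensing genes, OAS3 had a log2 fold of 1.23 with SAMD4B (the only one of the 3 at an unadjusted p under 0.05), EIF2AK2 0.07 and ADAR 0.01. For immune checkpoints and evasion, HLA-C had 0.65 (unadjusted p = 0.0964 in edgeR) and the poliovirus receptor PVR 0.19. Lipoprotein handling gave APOA2 -0.11 and LRP1 0.25, lipid synthesis ACLY -0.04 and SCD -0.10, and glycolysis ALDOA -0.11 and GAPDH -0.17. Nm enzymes and box C/D core genes gave the cap methyltransferase CMTR1 0.09, TRMT13 0.15 and NOP56 -0.12. Of the lists of mitochondrially encoded genes, hepatocyte markers and HeLa, immune and fibroblast markers, 0 genes matched a symbol of the deposited table, although 35 sites lay on the mitochondrial chromosome.

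In the authors' deposited table, 198 sites had p under 0.05 and the mean fold over input was 1.204 times higher with SAMD4B, although its median over sites was not. A higher share of reads counted at the sites was argued against as the source of a difference of that size, since the mean fraction differed by -0.0006 (0.004 over sites above 0 in all 6 libraries) and the pooled share was 84.7% against 83.9%. The nearly empty control inputs are a candidate explanation: with 1 pooled input for all 6 libraries the ratio of means was 1.0109, and 80 sites had p under 0.05, of which 27 were among the 198. With control input 2 used for the 3 control libraries, 669 sites had p under 0.05 and the ratio was 0.975. There 1 input served all 3 control libraries, while each SAMD4B+APOA2 library kept its own. The error of that 1 input then counts as a difference between the groups, so the 669 sites are no measure of an effect of SAMD4B. A smaller effect of SAMD4B on the pooled share of reads counted, higher in each of its 3 libraries (exact p = 0.1), stays open.

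The highest count was 37 in each Nm-seq library and 34 to 36 in the 4 usable inputs, and replicates lay closer together than sampling noise. Whole reads with sampling noise alone were argued against: Poisson noise around the site means would give 140.9 values above 37 in the Nm-seq libraries, and 0 were seen. A limited number of distinct reads per site could give both features, and variance over mean fell from 0.96 at a mean of 2.53 counts to 0.095 at 32.4. The largest departure from the form that such a limit would give was 0.232, between the bounds set for and against it, which keeps it open. No biological explanation was tested.

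Sites of small RNA genes were higher in input than in Nm-seq, at 110 snoRNA and snRNA sites. TMM scaling was argued against, since 98.2% as many were called without it. Mature RNA 3′ ends, which oxidation removes unless methylated, may be a source but stay open: of 35 input-higher sites in rRNA and other non-coding genes, 25.7% (9) lay on the annotated 3′ end and 0 on the 5′ end, against 2 of the 25 other tested sites of these genes (Fisher's exact p = 0.101, two-sided). Among snoRNA and snRNA sites, where the pattern was seen, it was 42 of 110 against 1 of 15 (Fisher's exact p = 0.0186). The sources do not say which end of a read was counted. If it was the 3′ end, hardly any site could lie on the 5′ end of an RNA. The 0 sites on the 5′ end then add nothing to the explanation. No biological explanation was tested.

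For the comparisons between the conditions, the 10 splits of the 6 libraries are too few for a share under 0.05; the real split called 0 sites and 0 genes and the highest other 0, so that 10 of the 10 splits gave as many. For Nm-seq against input in the 6 SAMD4B+APOA2 libraries, the 10 splits are again too few; the real split called 999 sites and the highest other 0, so that 1 split gave as many.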
